A study of Arabidopsis thaliana with 44 samples.

How the data were processed

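RNA of freshly harvested dry Arabidopsis seed was measured on 44 arrays. Near isogenic lines (NILs) share a common background and carry a chromosome segment at a named locus from another accession. The 3 lines here are named for the DELAY OF GERMINATION loci DOG1, DOG3 and DOG6, which affect seed dormancy. Plants that gave the seed grew at 15C, at 20C, under low nitrate (N0), under low light (LL) or under standard light (SL). Per the labels, 20C is the control for 15C and for N0, and SL is the control for LL. Each of the 15 combinations of line and condition had 3 arrays, except NIL DOG3 under N0 with 2. The labels describe the replicates of a group as biological, each a bulk of plants. The samples are labelled as total RNA, while the extraction protocol in the labels also describes RNA from polysomes.

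The values are log2 values deposited by the authors, made with RMA per the submitters' processing notes. RMA is a method of background correction, quantile normalization and probe summary. The RMA version, the array annotation and the genome build are not given in the sources used here. The deposited table has 27827 probe sets, each named for an Arabidopsis locus. Array medians lay between 4.22 and 4.39 and single values between 1.07 and 12.95. Gene symbols were taken from a table of the assembly TAIR10.1, which listed 27241 of the loci and gave a symbol for 10556. The other 586 loci kept their locus name. No pair of arrays held identical values. Pearson correlations over all probe sets were 0.987 to 0.994 between arrays of the same group and 0.974 to 0.994 between groups. The values of 182 probe sets were identical to those of another probe set on every array, so such loci cannot be told apart. RMA applies quantile normalization, which gives all arrays nearly the same distribution, so a change of total RNA amount would not be seen.

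Group means of all 15 groups were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a filter on dim probe sets and without a replicate block. With 29 residual degrees of freedom, the median residual SD was 0.199 on the log2 scale. Each condition was compared with its control within each NIL and as the mean of the 3 within-NIL differences. The NILs were compared pairwise as the mean of the 5 within-condition differences. A moderated F test asked whether the response to a condition differed between the NILs. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 27827, with no fold threshold. Adjusted p-values are from limma unless another test is named. With no change at all, a share of about 0.05 of the 27827 would have an unadjusted p under 0.05. Counts at an unadjusted p are therefore no sign of change by themselves. The number of arrays limits the precision. The median SE was 0.0922 for the mean comparisons of 15C and LL, 0.096 for N0, 0.16 for a comparison within a NIL, and 0.179 for N0 in NIL DOG3. Errors given after ± are SE unless said otherwise.

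Named genes followed a rule fixed before the data were examined. In each mean comparison of conditions these were the 10 largest rises and the 10 largest falls among called probe sets with the same direction in the 3 NILs, and up to 4 called members with the largest change in each gene list. Each NIL pair gave the 6 largest differences per direction, and each test of NIL by condition the 6 smallest p. The DOG1 gene was reported in every comparison. Not every gene that the rule gave is named in the text. The 23 gene lists fixed beforehand held 380 members, of which 376 were used. The other 4 were left out because neither the symbol nor a synonym in the TAIR10.1 table matched the listed name. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. Called probe sets of the NIL pairs were counted by chromosome with Fisher's exact test. Windows of fixed length in base pairs had been planned, but no genome build was named, so neighbouring genes were counted in runs of 200 measured genes in locus order. The order by locus number and the order in the TAIR10.1 table had rank correlations of 0.996 on chromosome 3 and 1 on the others.

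Because 15C and N0 share the 20C arrays, 100 sets of unchanged 15C, N0 and 20C arrays were simulated, with the simulated 20C arrays shared by both comparisons. These had the real residual SDs and no correlation between genes. The real 20C arrays were also split between the comparisons in 6 ways. A pollen index was computed per array as the mean centred log2 value of 25 genes with known pollen expression. This list, and a list of 9 tapetum and pollen coat genes, were written after the genes lowest in LL had been seen. None of these genes is in another list (0 and 0). Of the pollen markers 10, and of the tapetum genes 1, had a mean in LL above the median of all probe sets (4.28). The index was compared between conditions by exact relabeling of arrays within NILs. Alternatives were a replicate block, only the arrays of the groups compared, array weights (statmod 1.5.0 was loaded), a second quantile normalization, a trended and robust variance, removal of dim probe sets, and removal of each array in turn. Other alternatives, chosen after seeing the data, were the pollen index as a covariate, removal of the 3 SL arrays numbered 2, and removal of the 2 arrays of lowest weight.

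The fits were tested on simulated data drawn with the real probe set means and residual SDs. For the mean comparison of 15C, 83.6% of changes of 0.5 log2, 98.5% of changes of 1 log2 and 100% of changes of 2 log2 were recovered, and 7.84% of calls were false. For 15C in NIL DOG1 the shares recovered were 31.3%, 88.1% and 100%. For NIL by condition at 15C they were 7.46%, 58.2% and 98.5%, so small differences in response between the NILs were mostly missed.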

Results

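Seed transcriptomes were compared on 44 arrays, in 15 groups formed by 3 NILs and 5 growth conditions of the mother plant. Each group had 3 arrays, except NIL DOG3 under N0 with 2. Each array gave a log2 value for 27827 probe sets. A mean comparison set 9 arrays against 9, or 8 against 9 for N0.

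The DOG1 gene (AT5G45830), a major regulator of seed dormancy, was 4.73-fold higher in seed grown at 15C than at 20C (log2 change 2.24 ± 0.10, adjusted p = 1.03e-17). In NIL DOG1 its level went from 7.65 ± 0.07 (SD, n = 3) at 20C to 9.37 ± 0.03 (SD, n = 3) at 15C. It went from 6.12 ± 0.33 (SD, n = 3) to 8.71 ± 0.16 (SD, n = 3) in NIL DOG3, and from 6.08 ± 0.14 (SD, n = 3) to 8.49 ± 0.17 (SD, n = 3) in NIL DOG6. N0 raised DOG1 1.69-fold (0.76 ± 0.10, adjusted p = 1.54e-06), though within NIL DOG1 the change of 0.55 ± 0.17 did not pass (adjusted p = 0.0878). Under LL it differed from SL by 0.05 ± 0.10 (adjusted p = 0.848). The DOG1 signal was higher in NIL DOG1 than in the other lines in every condition, by 1.53 ± 0.17 over NIL DOG3 and 1.57 ± 0.17 over NIL DOG6 at 20C, and a sequence difference under its probes is not excluded as a source of this difference between lines. The smallest such difference was 0.65 ± 0.17 over NIL DOG3 at 15C (adjusted p = 0.0251). No difference between the NILs in the response of DOG1 passed the moderated F test over all probe sets. The adjusted p was 0.47 for 15C, 0.955 for N0 and 0.844 for LL. DOG1 had been fixed beforehand for report, and taken alone its unadjusted p in this test was 0.00242 for 15C. For N0 and LL the unadjusted p was 0.226 and 0.254. At 15C DOG1 rose 3.29-fold in NIL DOG1, 6.04-fold in NIL DOG3 and 5.33-fold in NIL DOG6. An equal response of the lines to 15C is therefore not shown.

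**Figure D1:**
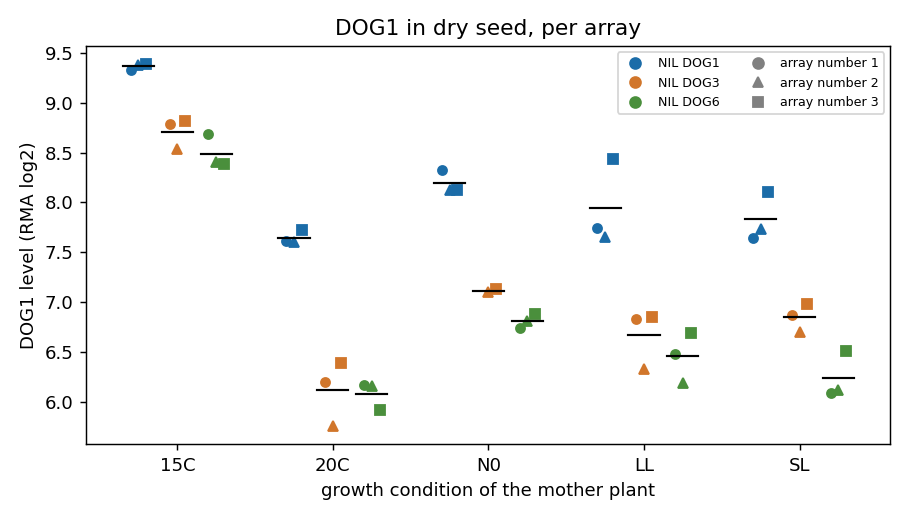
DOG1 level (RMA log2, y axis) on each array by growth condition (x axis), coloured by NIL, with array number as marker shape and a bar at each group mean. Means at 15C were 9.37, 8.71 and 8.49 in NILs DOG1, DOG3 and DOG6, against 7.65, 6.12 and 6.08 at 20C.

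The comparison of 15C with 20C asked how a cooler environment of the mother plant altered the seed transcriptome. BGLU28, a beta-glucosidase known from sulphur limitation, rose 7.10-fold (2.83 ± 0.21), and LSU1, a gene named for its response to low sulphur, rose 4.90-fold (2.29 ± 0.21). The growth-regulating factor gene GRF7 rose 4.98-fold (2.32 ± 0.07) and the sugar transporter gene SWEET10 4.83-fold (2.27 ± 0.13). ORS1 and ACS7, which encodes an enzyme of ethylene synthesis, rose 3.92-fold each, and AT4G01985, AT5G45280 and AT2G38380 rose 4.45-fold, 4.19-fold and 4.17-fold. SSL4, named for its similarity to strictosidine synthase, was 7.27-fold lower at 15C (-2.86 ± 0.17). Other large falls were those of AT4G34419 (3.76-fold), AT1G78170 (3.63-fold), PIFI (3.45-fold), AT5G62720 (3.31-fold), the nitrate reductase gene NIA1 (3.31-fold, -1.73 ± 0.13), UGT71B1 (3.22-fold), AGAL1 (3.04-fold), the embryo homeobox gene WOX2 (2.92-fold) and the plastid locus ATCG00250 (2.91-fold). The lower levels of SWEET10, AT4G01985, AT2G38380, ACS7, SSL4, AT1G78170, UGT71B1 and AGAL1 lay below the array medians, so the size of their changes depends on the background. In all, 7038 probe sets were called, 3488 higher and 3550 lower, of which 155 and 68 changed at least 2-fold. The direction was the same in the 3 NILs for 6830 (97.0%), a share that their choice by the mean favours, and effects of all probe sets correlated between NILs at 0.614 to 0.663. Within NILs DOG1, DOG3 and DOG6, 2707, 2557 and 3255 probe sets were called, and 1208 were called in all of them. With only the arrays of the groups compared in the fit, these became 1314, 1241 and 1925.

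Genes of abscisic acid (ABA), the hormone that maintains dormancy, changed at 15C. In the list of ABA perception and signalling, 13 of 24 members rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.000303). The phosphatase genes ABI2 and ABI1 rose by 0.80 ± 0.06 and 0.77 ± 0.07, while ABI4, a transcription factor gene, changed by -1.05 ± 0.11 and the receptor gene RCAR3 by -0.96 ± 0.11. ABI1 and ABI2 are known to act against ABA signalling. Of ABA synthesis genes, NCED3 rose by 0.93 ± 0.14, NCED6 by 0.75 ± 0.12 and NCED2 by 0.53 ± 0.13, and of the 9 members 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0758, not passed). The ABA breakdown genes CYP707A1 and CYP707A3 rose by 1.11 ± 0.16 and 0.40 ± 0.11, while CYP707A2 fell by 0.58 (2 up and 1 down of 4, also adjusted over the list alone; camera adjusted p = 0.501). GA2OX6 and GA2OX2, which encode enzymes that inactivate gibberellin, rose by 1.59 ± 0.11 and 0.83 ± 0.10. The gibberellin metabolism list had 2 members up and 2 down of 15 (the same adjusted over the list alone; camera adjusted p = 0.844), and its median, -0.10, and mean, 0.05, differed in sign.

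Dormancy and maturation regulators had 11 of 25 members higher and 4 lower at 15C (11 and 4 adjusted over the list alone; camera adjusted p = 0.0266). Besides DOG1, MFT (E12A11 in the gene table) rose by 0.73 ± 0.08 and BZIP67 (DPBF2) by 0.63 ± 0.12, while PIF1 (PIL5), a light-regulated repressor of germination, changed by -0.97 ± 0.09. Nitrogen assimilation genes fell on balance, with 5 of 23 up and 11 down (5 and 11 adjusted over the list alone; camera adjusted p = 0.00348). Examples besides NIA1 were UPM1 (-1.41 ± 0.10) and the nitrite reductase gene NIR1 (-1.36 ± 0.13). The sulphur limitation list had 10 of 12 members up and 0 down (10 and 0 adjusted over the list alone; camera adjusted p = 9.58e-10), among them the sulphate transporter gene SULTR1;2 (1.33 ± 0.16) and ATSDI1 (1.05 ± 0.10). Heat shock genes fell on balance, with 1 up and 10 down of 19 (1 and 12 adjusted over the list alone; camera adjusted p = 2.54e-06), including HSP17.6II (-1.18 ± 0.10) and the heat shock factor gene HSFA2 (-1.09 ± 0.10). In the cold response list 8 of 22 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0133), including COR413-PM1 (0.97 ± 0.08) and CBF4 (0.80 ± 0.14), with GRP7 at -0.86 ± 0.08.

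Flavonoid and proanthocyanidin genes had 7 of 21 up and 0 down at 15C (7 and 0 adjusted over the list alone; camera adjusted p = 0.0113), including the laccase-like gene TT10 (0.84 ± 0.09) and TT5 (0.67 ± 0.11). Ethylene genes had 6 of 14 up and 1 down (6 and 1 adjusted over the list alone; camera adjusted p = 0.0133), with the ACC oxidase gene EFE higher by 1.07 ± 0.17 and the ethylene receptor gene ERS2 by 0.83 ± 0.08. The ethylene call was lost with an estimated correlation (adjusted p = 0.0665 with an estimated correlation). The other 7 calls held with it, at adjusted p from 0.00112 for sulphur limitation to 0.0383 for cold response. Among lists that did not pass, seed coat and mucilage genes had 3 of 10 higher (camera adjusted p = 0.109), seed storage proteins and oleosins 3 of 13 lower (0.177), late embryogenesis abundant genes 1 of 15 higher (0.501), endosperm genes 1 of 8 higher (0.639) and photosynthesis genes 2 higher and 2 lower of 24 (0.850). Clock genes had 4 higher and 2 lower of 21 (0.434), light signalling 3 and 6 of 23 (0.371), gibberellin signalling 2 and 1 of 9 (0.501), nitrate transport and signalling 4 and 4 of 26 (0.844), sugar genes 4 and 2 of 16 (0.354), wall loosening and reserve mobilization 1 and 2 of 12 (0.371) and antioxidant genes 2 and 4 of 11 (0.823). Adjusted over the list alone, the counts of these 12 lists were the same except for 4 seed storage genes and 5 nitrate transport and signalling genes lower. The mean index of pollen markers differed from that of 20C by -0.40 on the log2 scale at 15C (exact two-sided p = 0.00225, adjusted p = 0.00338 over 3 comparisons; n = 9 and 9), and of 25 markers 4 were called lower and 21 were not called (camera p = 0.000979; p = 0.313 with an estimated correlation). With the index as a covariate, 6321 probe sets were called, 6052 of them shared.

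**Figure D2:**
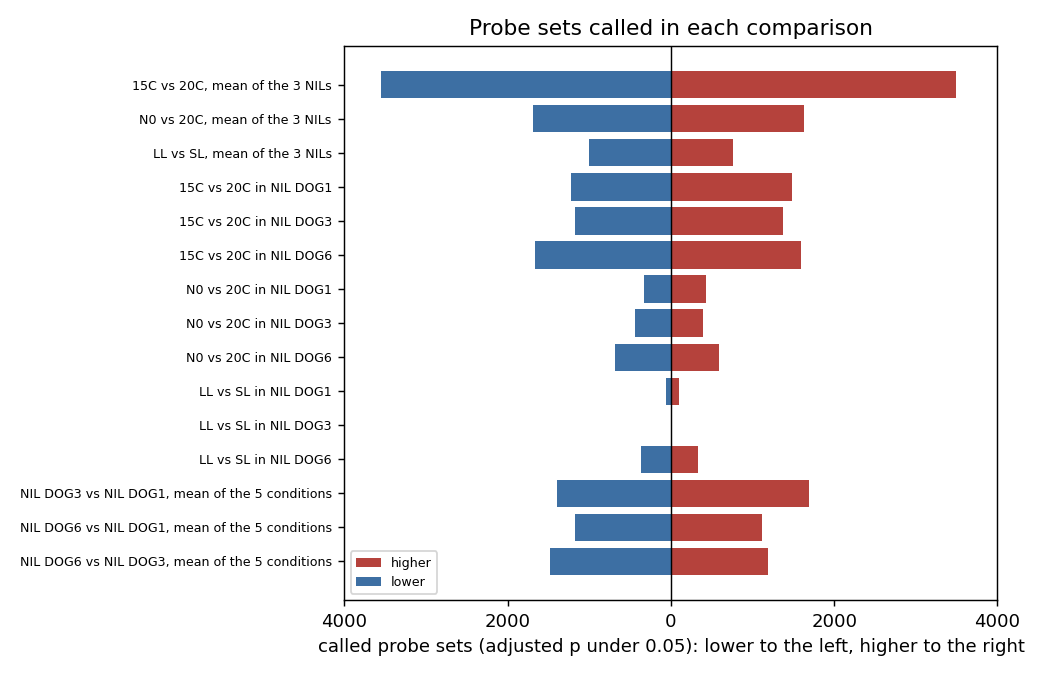
Called probe sets (adjusted p under 0.05) per comparison, lower to the left and higher to the right of 0 on the x axis, with the comparisons on the y axis. The mean comparison of 15C called 3488 higher and 3550 lower, N0 1632 and 1688, and LL 759 and 1010.

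N0 against 20C addressed the nitrate supply of the mother plant. The nitrilase gene NIT4 rose 4.44-fold (2.15 ± 0.19), BGLU28 3.67-fold (1.87 ± 0.21) and LSU1 3.32-fold (1.73 ± 0.22). AT3G15250 (2.93-fold), GRF7 (2.88-fold), ACR6 (2.75-fold), AT3G49160 (2.68-fold), the allantoinase gene ALN (2.58-fold), AT1G30190 (2.48-fold) and CBF4 (2.45-fold) followed. COL5, of the CONSTANS-like family, was 5.75-fold lower (-2.52 ± 0.21), AT4G39780 4.74-fold and AT4G34419 4.73-fold. Falls from 3.93-fold to 3.07-fold were those of WOX2, SSL4, AT5G05965, BUB3.2, the GATA factor gene CGA1 (-1.62 ± 0.10), AT5G26010 and AT5G42830. The lower levels of NIT4, CBF4, COL5 and BUB3.2 lay below the array medians, so the size of their changes depends on the background. The test called 3320 probe sets, 1632 higher and 1688 lower, with 22 and 75 at least 2-fold apart. In 3240 (97.6%), again chosen by their mean, the 3 NILs had the same direction, and effects of all probe sets correlated between NILs at 0.421 to 0.465. Within NILs DOG1, DOG3 and DOG6 the counts were 764, 824 and 1272, of which 319 were common to all, and with only the arrays of the groups compared they were 233, 75 and 90.

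Genes of nitrogen assimilation fell on balance under N0. Their list had 4 of 23 up and 10 down (4 and 11 adjusted over the list alone; camera adjusted p = 9.85e-06). NIR1 changed by -1.53 ± 0.14, NIA1 by -1.48 ± 0.14, UPM1 by -1.42 ± 0.10 and G6PD2 by -1.11 ± 0.11. Nitrate transport and signalling genes went both ways, 5 up and 5 down of 26 (5 and 7 adjusted over the list alone; camera adjusted p = 0.860). The nitrate transporter gene NRT1.1 rose by 1.19 ± 0.12, while AT1G68670 (HHO2) changed by -1.40 ± 0.10, LBD39 by -1.23 ± 0.12 and BT2 by -0.85 ± 0.20. Sulphur limitation genes rose in 9 of 12 members, with 0 lower (10 and 0 adjusted over the list alone; camera adjusted p = 3.17e-11), SULTR1;2 by 1.00 ± 0.16 and ATSDI1 by 0.90 ± 0.11. Photoreceptor and light signalling genes fell on balance, with 1 up and 7 down of 23 (2 and 9 adjusted over the list alone; camera adjusted p = 0.00452), including PIF5 (PIL6, -1.09 ± 0.12), PIF1 (-0.89 ± 0.10), PHYA (-0.53 ± 0.07) and HY5 (-0.42 ± 0.07). The calls of nitrogen assimilation, sulphur limitation and light signalling held with an estimated correlation, at adjusted p = 0.0032, 0.000421 and 0.0299.

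The ABA perception and signalling list had 9 of 24 up and 3 down under N0 (10 and 4 adjusted over the list alone; camera adjusted p = 0.00662; adjusted p = 0.118 with an estimated correlation), with HAI2 at 0.67 ± 0.07, ABI2 at 0.66 ± 0.06 and ABI4 at -0.75 ± 0.11. Seed storage genes had 1 of 13 up and 3 down (1 and 4 adjusted over the list alone; camera adjusted p = 0.00298; adjusted p = 0.335 with an estimated correlation). The 3 were albumin genes, SESA2 (-0.69 ± 0.09), SESA4 (-0.66 ± 0.10) and SESA1 (-0.58 ± 0.07), and the oleosin gene OLEO3 was higher by 0.30 ± 0.05. Heat shock genes had 9 of 19 up and 1 down (11 and 2 adjusted over the list alone; camera adjusted p = 0.0139; adjusted p = 0.318 with an estimated correlation), with HSP17.6II higher by 0.60 ± 0.10 and HSFA2 at -0.44 ± 0.10. In lists that did not pass, TPS8 and TPS9, of trehalose metabolism, changed by -0.79 ± 0.08 and -0.71 ± 0.08 (sugar list, 3 up and 3 down of 16; camera adjusted p = 0.909), PRR5 of the clock by -0.84 ± 0.12 (5 and 3 of 21; 0.909) and CYP707A2 by -0.72 ± 0.09 (ABA breakdown, 1 and 1 of 4; 0.957). ABA synthesis had 2 up and 0 down of 9 (0.184), gibberellin metabolism 2 and 1 of 15 (0.957), gibberellin signalling 0 and 1 of 9 (0.909), dormancy regulators 7 and 3 of 25 (0.450), cold response 2 and 1 of 22 (0.450) and flavonoid genes 0 and 1 of 21 (0.957). Late embryogenesis abundant genes had 1 and 1 of 15 (0.957), photosynthesis 1 and 3 of 24 (0.206), wall loosening 0 and 2 of 12 (0.197), antioxidant genes 1 and 3 of 11 (0.0763), ethylene 3 and 2 of 14 (0.957), and seed coat and endosperm genes 0 called by limma of 10 and of 8 (0.450 and 0.779). Adjusted over the list alone, ABA synthesis had 2 up and 1 down, ABA breakdown 2 and 1, gibberellin signalling 1 and 2, clock genes 6 and 4, wall loosening 0 and 3 and ethylene 4 and 5, with the other lists of these 3 sentences the same. The pollen index differed by 0.0081 between N0 and 20C (exact two-sided p = 0.963; n = 8 and 9).

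**Figure D3:**
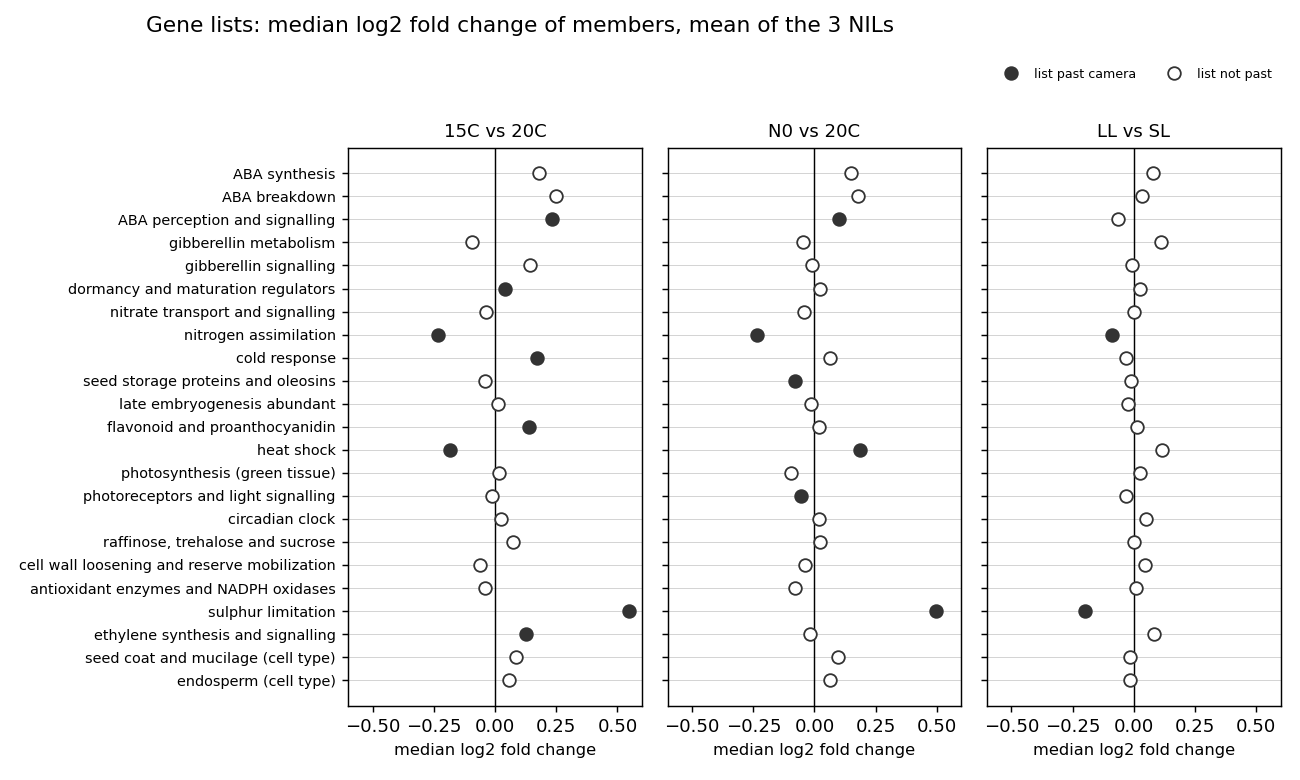
Median log2 fold change of the members of each of the 23 gene lists (y axis) in the mean comparisons of 15C, N0 and LL (panels); filled points passed camera and open points did not. Sulphur limitation genes had medians of 0.55 at 15C, 0.50 under N0 and -0.20 under LL.

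The 15C and N0 responses were set against each other. GRF7, BGLU28 and LSU1 were among the largest rises in both, and SSL4, AT4G34419 and WOX2 among the largest falls. Calls overlapped in 1180 probe sets higher in both, against 205 expected of independent lists, and in 1200 lower in both, against 215, while 56 had opposite directions. Across genes, which are not independent replicates, the changes correlated at r = 0.654. Simulated unchanged groups that shared simulated 20C arrays, with independent genes, gave a mean r of 0.481. The covariance was 0.035, against 0.0057 in the simulation, a difference of 0.0293. With the 20C arrays split between the comparisons in 6 ways, the covariance lay between 0.0269 and 0.0309, 521 to 732 probe sets were higher in both (73.1 to 98.5 expected), and 446 to 690 lower in both (70.6 to 102 expected). Heat shock genes were the list that passed in both with opposite directions, and its N0 call was lost with an estimated correlation (adjusted p = 0.318 with an estimated correlation).

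The comparison of LL with SL addressed the light level of the mother plant. Pollen markers moved with this comparison. AGP23, which encodes an arabinogalactan protein, was 4.02-fold lower (-2.01 ± 0.35). AT5G26717 (4.02-fold), AT3G28750 (3.94-fold), AT3G07820 (3.93-fold), AT1G78460 (3.68-fold), AT3G01270 (3.58-fold), AT3G62180 (3.42-fold) and AT3G05610 (3.41-fold) were also lower. The index differed between LL and SL by -0.80 (exact two-sided p = 0.0015, adjusted p = 0.00338; n = 9 and 9), and 12 of 25 pollen markers were called lower (camera p = 1.33e-16; p = 0.0153 with an estimated correlation), among them AGP6 (-1.71 ± 0.32) and VGD1 (-1.47 ± 0.33). The marker list was written after the genes lowest in LL had been seen, which favours a small p in this comparison. Without the 3 SL arrays numbered 2 the index differed by -0.43 (exact two-sided p = 0.008). LSU1 (3.44-fold lower, -1.78 ± 0.21) and AT1G12030 (3.31-fold lower, -1.73 ± 0.16) fell too. The rises were led by the germin-like protein genes AT5G39110 (1.89 ± 0.32) and GLP6 (1.43 ± 0.24), the NAC factor gene NAC042 (1.28 ± 0.22) and AT1G66690 (1.14 ± 0.22). MSL9, of a mechanosensitive channel family, rose by 1.09 ± 0.09, and AT5G33300, the calmodulin-like gene TCH3, AT3G45310, CYP71B22 and GSTF7 rose by 1.08 to 1.00. The lower levels of LSU1, AT3G05610, AT1G66690, MSL9, AT5G33300 and TCH3 lay below the array medians, so the size of their changes depends on the background.

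LL changed 1769 probe sets, 759 higher and 1010 lower, of which 10 and 124 differed at least 2-fold. The 3 NILs had the same direction in 1690 (95.5%), a share that the choice of probe sets by their mean over the NILs favours, and over all probe sets the LL effects correlated between NILs at 0.253 (DOG1 and DOG3), 0.388 (DOG1 and DOG6) and 0.449 (DOG3 and DOG6). Within NILs DOG1, DOG3 and DOG6, 161, 4 and 695 were called, 3 of them in every NIL, and none with only the arrays of the groups compared (0, 0 and 0 by limma; 2979, 2112 and 4495 had an unadjusted p under 0.05 in the fit of all arrays). With the pollen index as a covariate 587 were called, 529 of them shared, with 292 higher and 295 lower and 12 and 4 of them at least 2-fold. The count was 856 without the 3 SL arrays numbered 2, and 844 with only the arrays of the groups compared. Of the 113 genes at least 2-fold lower that were not markers, 108 (95.6%) followed the index from array to array within groups (r over 0.6), against 1.05% of all probe sets. The SL arrays numbered 2 of NILs DOG1 and DOG3 had an index of 1.22 and 1.39, against -0.25 to 0.06 on the others of these groups. They stood furthest from their group means and also enter the SL means by which these genes were chosen. This favours a high share, which was not counted without these arrays. Of all calls that were not markers 19.2% of those lower and 0% of those higher followed the index, and with the index as a covariate their median change went from -0.32 to -0.27 and stayed at 0.36. Of the 759 higher calls 271 stayed called, while the SE grew with the covariate, from 0.09 to 0.12 for MSL9. With the index as a covariate, AGP23 was at -0.56 ± 0.19 (adjusted p = 0.118) and AT5G26717, AT3G28750, AT3G07820, AT1G78460, AT3G01270, AT3G62180 and AT3G05610 were not called either (adjusted p = 0.0625 to 0.865), while LSU1 (-1.52 ± 0.26, adjusted p = 0.00138), AT1G12030 (-1.63 ± 0.21) and MSL9 (1.17 ± 0.12) stayed called. AT1G66690 (0.80 ± 0.27), CYP71B22 (0.91 ± 0.26) and GSTF7 (0.92 ± 0.33) changed less in size than AGP23 and were not called (adjusted p = 0.121, 0.0568 and 0.147). GSTF7 was also lost without the SL arrays numbered 2.

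**Figure D4:**
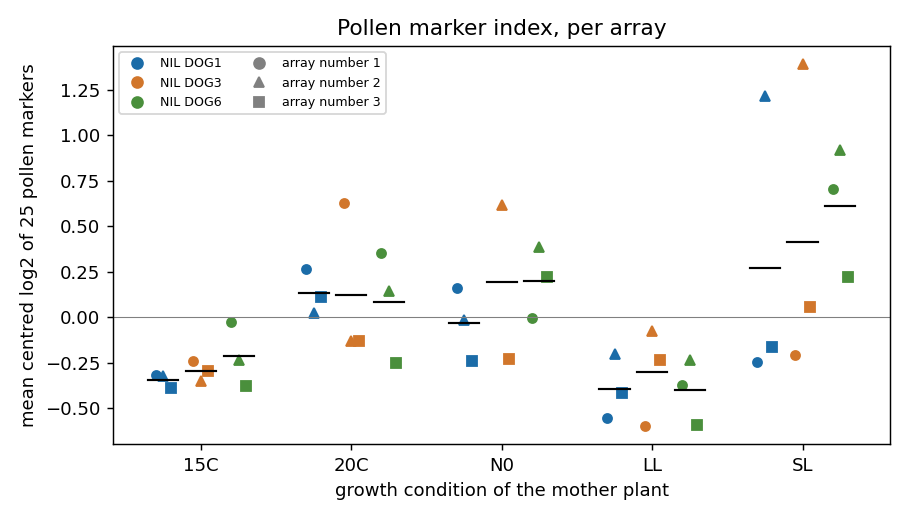
Pollen marker index (mean centred log2 of 25 markers, y axis) on each array by growth condition (x axis), coloured by NIL, with array number as marker shape and a bar at each group mean. SL arrays reached 1.39 and averaged 0.43, while LL arrays averaged -0.36 with a highest value of -0.07.

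Nitrogen assimilation genes were lower on balance under LL, with 0 up and 3 down of 23 (0 and 3 adjusted over the list alone; camera adjusted p = 0.0105; adjusted p = 0.172 with an estimated correlation). The ammonium transporter gene AMT1;1 changed by -0.81 ± 0.08 and the glutamine synthetase gene GSR 1 by -0.45 ± 0.10, while the call of NIA1 (-0.44 ± 0.13) was lost in 12 of the 18 fits that each left out 1 array. Sulphur limitation genes had 1 of 12 up and 6 down (1 and 6 adjusted over the list alone; camera adjusted p = 0.00775; adjusted p = 0.172 with an estimated correlation), with ATSDI1 at -0.42 ± 0.10, a call lost with the pollen index as a covariate. The calls of BGLU28 (-0.76 ± 0.21) and SULTR1;2 (-0.53 ± 0.16) were lost in 5 and 9 of those 18 fits. These calls and that of NIA1 were also lost with the pollen index as a covariate, those of BGLU28 and SULTR1;2 with only the arrays of the groups compared, and those of NIA1 and SULTR1;2 without the SL arrays numbered 2. With the pollen index as a covariate the camera adjusted p was 0.00798 for nitrogen assimilation and 0.112 for sulphur limitation. Heat shock genes had 5 up and 1 down of 19 (8 and 3 adjusted over the list alone; camera adjusted p = 0.137, not passed), with HSFA7A higher by 0.69 ± 0.15, lost with the index as a covariate, and HSFA2 by 0.50 ± 0.10. RGL2, a DELLA repressor of germination, rose by 0.63 ± 0.09, BME3 by 0.60 ± 0.12, ABI4 by 0.59 ± 0.11 and the ethylene receptor gene ERS1 by 0.58 ± 0.08. NRT2.5, of the nitrate transporter family, changed by -0.55 ± 0.10 and CYP707A2 by -0.37 ± 0.09, the latter no longer called with the index as a covariate. The clock list had 5 up and 2 down of 21 and light signalling 2 and 3 of 23 (5 and 3, and 2 and 5, adjusted over the list alone; camera adjusted p = 0.462 and 0.354). With the index as a covariate the calls up and down were 0 and 1 for the clock, 0 and 2 for light signalling and 2 and 1 for heat shock, and with 1 array left out 3 to 7 clock and 2 to 7 light signalling members were called.

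In the remaining lists under LL, none of which passed, nitrate transport and signalling had 1 member up and 4 down of 26 (camera adjusted p = 0.462), dormancy regulators 2 and 2 of 25 (0.900), ABA signalling 2 and 0 of 24 (0.462), gibberellin signalling 1 and 0 of 9 (0.523) and ethylene 1 and 0 of 14 (0.354). ABA breakdown and sugar genes had 1 down each (0.734 and 0.462), and flavonoid, wall loosening, antioxidant and seed coat genes 1 up each (0.900, 0.354, 0.415 and 0.900). No member was called by limma in ABA synthesis, gibberellin metabolism, cold response, seed storage, late embryogenesis abundant, photosynthesis or endosperm genes, at camera adjusted p from 0.354 to 0.939. Adjusted over the list alone, nitrate transport and signalling had 3 up and 6 down, dormancy regulators 2 and 4, sugar genes 0 and 2, flavonoid and antioxidant genes 2 and 0 each and wall loosening 3 and 0, with the other lists of this paragraph the same. With 1 array left out, 2 to 4 dormancy regulators and 4 to 7 members of nitrate transport and signalling were called, and with the index as a covariate 1 up and 0 down, and 0 up and 4 down. The flavonoid, wall loosening and seed coat calls were lost with the index as a covariate, and also with only the arrays of the groups compared.

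NIL by condition tests asked whether the response differed between the lines. At 15C, 11 probe sets were called. AT3G24450 was higher by 1.39 ± 0.14 in NIL DOG6, with -0.04 ± 0.14 in NIL DOG1 and -0.30 ± 0.14 in NIL DOG3 (adjusted p = 1.84e-05). AT5G09480 had 2.52 ± 0.24, 0.23 ± 0.24 and 2.22 ± 0.24 in NILs DOG1, DOG3 and DOG6 (adjusted p = 0.00118), and AT2G38380 2.58, 0.79 and 2.80, each ± 0.22 (adjusted p = 0.00183). AT5G60260 changed by -1.34 ± 0.18 in NIL DOG3, against 0.15 and 0.16 in the other lines (adjusted p = 0.0038). TT10 had 1.66, 0.30 and 0.56, each ± 0.16 (adjusted p = 0.012), and AT1G68240 -1.67, -0.66 and -1.29, each ± 0.12 (adjusted p = 0.017). All 15C and 20C levels of AT3G24450 and AT5G60260 lay below the array medians. So did the 20C levels of AT5G09480 and TT10, and those of AT2G38380 in NILs DOG3 and DOG6. The size of these differences depends on the background. The call of TT10 was lost without NIL DOG1 15C number 2 or NIL DOG1 20C number 1, and that of AT1G68240 without any of NIL DOG1 15C number 2, NIL DOG3 15C number 3, NIL DOG1 20C number 2, or NIL DOG3 20C numbers 1 and 3. With only the arrays of the groups compared, AT5G60260, TT10 and AT1G68240 were no longer called. N0 gave 0 calls by limma (1574 at an unadjusted p under 0.05; 1 after a second quantile normalization). LL gave 1, AT1G54575, at -2.40 ± 0.30 in NIL DOG6, 0.11 ± 0.30 in NIL DOG1 and 0.14 ± 0.30 in NIL DOG3 (adjusted p = 0.00962), which was lost without LL number 1, SL number 2 or SL number 3 of NIL DOG6, and with only the arrays of the groups compared. Its levels in NILs DOG1, DOG3 and DOG6 were 5.14, 5.53 and 7.06 in SL, and 5.25, 5.67 and 4.66 in LL. NIL DOG6 thus stood apart in the SL control as well as in LL.

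Comparison of the NILs with each other showed how the lines differ whatever the condition. AT5G42825 had a mean level of 10.36 in NIL DOG1 against 3.02 in NIL DOG3 and 2.80 in NIL DOG6 (differences of -7.33 ± 0.31 and -7.55 ± 0.30), and LUL1 (7.45 against 3.53 and 3.84), AT5G45440 and AT5G43620 (6.94 against 3.41 and 3.15) were also high in NIL DOG1. AT5G38780, AT4G19080, ABCI21 and AT5G46040 were low there, with AT5G38780 higher by 2.75 ± 0.06 in NIL DOG3 and by 2.47 ± 0.06 in NIL DOG6. NIL DOG3 stood apart in AT1G24388 (3.12 against 8.58 in NIL DOG1, a difference of -5.46 ± 0.09, and 8.61 in NIL DOG6), AT1G24390, AT1G27030, UGT85A5 and AT1G23780, all low, and in AT5G66053 (8.53 against 3.42 and 3.42), AT5G66052 and AT5G57567, all high. In NIL DOG6, AT3G18535 was at 3.83 against 8.92 in NIL DOG1 (a difference of -5.09 ± 0.07) and 8.80 in NIL DOG3, the expansin-like gene EXLA1 at 5.42 against 9.44 and 9.28, and hda17, AT3G29644 and AT3G44280 were low too, while hda10 and AT2G13665 were high. Apart from those of EXLA1, AT5G38780, UGT85A5 and AT1G23780, the low levels of these genes lay below the array medians, so the size of those differences depends on the background. Between NIL DOG3 and NIL DOG1, 3081 probe sets differed (1688 higher and 1393 lower in NIL DOG3), 158 of them at least 2-fold. NIL DOG6 against NIL DOG1 gave 2297 (1120 and 1177, 148 at least 2-fold), and NIL DOG6 against NIL DOG3 gave 2675 (1190 and 1485, 138 at least 2-fold). The DOG1 signal was 2.15-fold lower in NIL DOG3 and 2.61-fold lower in NIL DOG6 than in NIL DOG1, and 1.21-fold lower in NIL DOG6 than in NIL DOG3 (adjusted p = 0.0181).

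Genes at least 2-fold apart between NILs lay close together in locus order, while called genes as a whole were spread more widely, with 17, 11 and 14 in the median run of 200 measured genes for NIL DOG3 against NIL DOG1, NIL DOG6 against NIL DOG1 and NIL DOG6 against NIL DOG3. Chromosome 5 held 34.4% of the calls between NIL DOG3 and NIL DOG1 but 23.0% of the probe sets tested (odds ratio 1.91, Fisher's exact test, adjusted p = 6.18e-52). Chromosome 3 was enriched for both pairs with NIL DOG6, at odds ratios of 1.77 against NIL DOG1 (adjusted p = 2.43e-29) and 1.79 against NIL DOG3 (adjusted p = 2.75e-34), and chromosome 5 for NIL DOG6 against NIL DOG1 (1.52, adjusted p = 2.16e-17). Neighbouring genes are not independent, so these p-values are too small. Of the 139 runs of 200 measured genes, 15 held 5 or more of the 2-fold differences between NIL DOG3 and NIL DOG1, and together 128 of the 158. For NIL DOG6 against NIL DOG1 12 runs held 100 of 148, and against NIL DOG3 13 runs held 102 of 138. Runs with 8 or more lay between AT1G21360 and AT1G33860 in the pairs with NIL DOG3, between AT3G27840 and AT3G47550 in those with NIL DOG6, and in those with NIL DOG1 between AT5G40700 and AT5G45890, between AT4G18280 and AT4G20090, and between AT5G01010 and AT5G02830. The run that holds the DOG1 gene, AT5G44180 to AT5G45890, had 13 of the 2-fold differences between NIL DOG3 and NIL DOG1, 11 between NIL DOG6 and NIL DOG1, and 0 between NIL DOG6 and NIL DOG3. Gene order is that of the locus numbers; probe sequences were not analysed here, so a level can also reflect a sequence difference under the probes.

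**Figure D5:**
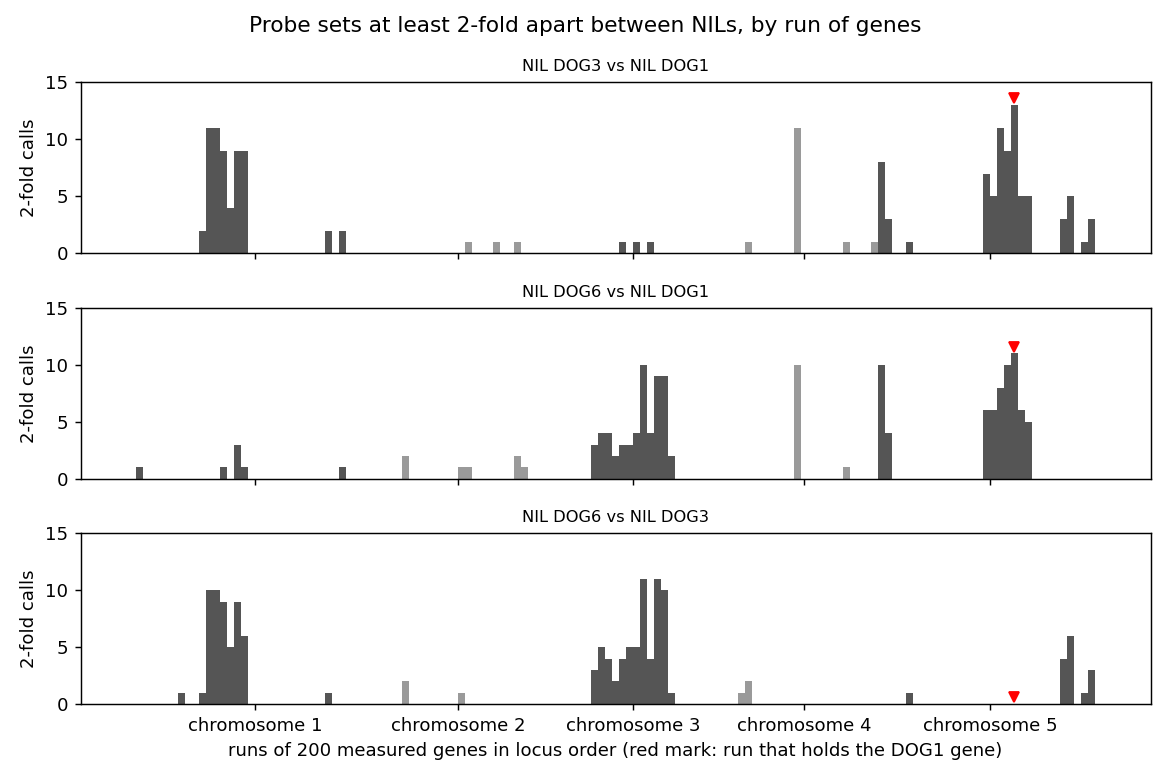
Called probe sets at least 2-fold apart (y axis) in each run of 200 measured genes along the 5 chromosomes (x axis), for the 3 NIL pairs (panels, shades alternate by chromosome); the red mark is the run that holds DOG1. The highest run held 13, 11 and 11 such probe sets, and the median run 0.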

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

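The tests of pollen RNA, of NIL DOG6 alone, of light against harvest and of random gene placing were chosen only after the results they address were seen, as was the pattern of N0 and LL effects. The relabeling of LL and SL was set after that pattern but before its own result was seen, and the question of probe sequence and the splits of the arrays were set before their results were seen. The response to 15C differed between the NILs in 11 probe sets, and the response to LL in 1, by a test of the difference itself. At 15C these were led by AT3G24450 (adjusted p = 1.84e-05), AT5G09480 (adjusted p = 0.00118), AT2G38380 (adjusted p = 0.00183), AT5G60260 (adjusted p = 0.0038), TT10 (adjusted p = 0.012) and AT1G68240 (adjusted p = 0.017). Under LL it was AT1G54575 (adjusted p = 0.00962).

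Other splits of the same arrays were counted for each number of calls, with 100 splits drawn. For NIL by condition, deviations from an additive fit of NIL and condition were shuffled within conditions instead, and each shuffle is counted as a split. Chance is argued against, though not excluded, where the real split alone (1 of 100) reached its count. That held for 15C (7038, highest other split 4410), N0 (3320 and 451), LL (1769 and 1022), NIL DOG3 against NIL DOG1 (3081 and 271), NIL DOG6 against NIL DOG1 (2297 and 689), NIL DOG6 against NIL DOG3 (2675 and 576) and NIL by condition at 15C (11 and 1). Chance cannot be excluded for NIL by condition under N0 (0 calls by limma, 1574 at an unadjusted p under 0.05, highest other 2, with 100 of 100 splits as large) or under LL (1, highest other 69, 16 of 100). What lies behind the shuffle with 69, several times the real count, was not examined. Within a NIL the 10 splits are too few for a share under 0.05. The real counts and highest others were 2707 and 2, 2557 and 1, and 3255 and 1 for 15C in NILs DOG1, DOG3 and DOG6, 764 and 0, and 1272 and 3 for N0 in NILs DOG1 and DOG6, and 161 and 3, 4 and 0, and 695 and 4 for LL.

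Genes at least 2-fold lower in LL than in SL may reflect pollen RNA in the seed samples in amounts that differ between arrays. Of these genes, markers left out, 95.6% followed the pollen index within groups, and their median change went from -1.29 to -0.22 (SD over genes 0.25 and 0.29) with the index as a covariate. Abundant pollen markers did not all move, with TUA1 (mean level 7.13) at 0.08 ± 0.08 and VGD1 (6.43) at -1.47 ± 0.33, while tapetum and pollen coat genes had 0 called by limma and a median of 0.04. TUA1 was called lower under N0 (-0.37 ± 0.08, adjusted p = 0.00209), where the index differed by 0.0081, so its level does not depend on the index alone. Of the 9 tapetum genes 1 lay above the median of all probe sets in LL, so a fall could hardly be seen. Neither therefore decides on pollen RNA. The 3 SL arrays numbered 2 do not alone account for the difference of the index, which was -0.80 with them and -0.43 without (exact two-sided p = 0.008). How many of the 2-fold lower genes stay so, or follow the index, without these arrays was not counted, and all LL calls went from 1769 to 856. These arrays enter both the SL means that chose the genes and the index within groups, which favours a high share that follows it. An effect of light on pollen RNA cannot be told apart from one of harvest or cleaning of the seed, since no value here separates them. The test of the index, LL against SL (exact two-sided p = 0.0015), does not separate them either. Of the 2-fold lower genes 5, AT1G12030, AT1G30190, AT1G72570, ACR6 and LSU1, did not follow the index and stayed called with it.

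Opposite signs of the N0 and LL effects, which share no arrays, are a pattern found in these data. Pollen RNA is argued against as its source, since 89.2% of the genes called in both that did not follow the index had opposite signs. A variation between seed batches that falls on the LL and SL labels by chance is argued against by 2 of 100 relabelings, the real one included, with a correlation as low (across all 27827 probe sets, which are not independent replicates: real -0.236, lowest other -0.240). Whether the pattern belongs to NIL DOG6 alone stays open, with correlations over the 26213 that did not follow the index of -0.0838 in NIL DOG1, -0.0328 in NIL DOG3 and -0.251 in NIL DOG6. A biological response to nitrate and light that runs in opposite directions is a hypothesis that these tests leave open and do not establish, and the pattern is not shown to be particular to nitrate, since 78.4% of the genes called in both 15C and LL also had opposite signs (15C and N0 share the 20C arrays).

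Differences of at least 2-fold between NILs gathered in runs of neighbouring genes. Random placing of these genes is argued against, since 0 of 1000 placings gave a run with as many 2-fold differences for any pair (highest random 9, 8 and 7 against 13, 11 and 11). A sequence difference under the array's probes cannot be told apart from a change of RNA, since each probe set is given as 1 summary value, and 81.0% of the 2-fold differences between NIL DOG3 and NIL DOG1 lay in runs with 5 or more. Introgressed segments, which the lines carry by design, may give both.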

How the results depend on the processing

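The pollen index as a covariate and the removal of 3 SL arrays or of the 2 arrays of lowest weight were chosen after seeing the data. Of 55 genes that the naming rule gave and that were called for LL, 29 lost their call with the pollen index, and 39 kept it in every fit set before the data were examined that included their probe sets, removal of 1 array included. The index itself differed between LL and SL, and the SE grew with it as a covariate (0.25 to 0.33 for GSTF7). A lost call alone therefore does not tie a change to pollen. None of the 55 changed sign in any fit. DOG1 under LL, which was not called, went from 0.05 to -0.03 with the pollen index, and some lists that did not pass for LL changed direction with it (cold response, flavonoid, photosynthesis and endosperm genes). Over the other choices of fit set before the data were examined, the mean comparisons called 6755 to 8014 (15C), 2726 to 3786 (N0) and 844 to 2056 (LL), and the NIL pairs stayed within 1.5 times their counts. The cause of the changes below was not tested. Fits with fewer arrays have fewer degrees of freedom, and the fit of all arrays takes the same spread for all groups. With only the arrays of the groups compared, 15C called 7258 against 7038 in the main fit. LL, with as many arrays, called 844 against 1769, so its main count depends on which arrays set the spread. Signal near background limits dim probe sets.

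With only the arrays of the groups compared, LL called 844. Within NILs DOG1, DOG3 and DOG6, 15C called 1314, 1241 and 1925, N0 233, 75 and 90, and LL 0, 0 and 0 by limma (2979, 2112 and 4495 at an unadjusted p under 0.05 in the fit of all arrays). NIL by condition gave 7 at 15C and 0 under LL (1855 at an unadjusted p under 0.05 in the fit of all arrays). Array weights gave 1342 for N0 and 380 for LL in NIL DOG1, and 29 for NIL by condition at 15C. Without dim probe sets LL called 280, 8 and 1077 within NILs DOG1, DOG3 and DOG6, NIL by condition at 15C 6, and the covariance of 15C and N0 was 0.0534. A second quantile normalization gave 1 for NIL by condition under N0. The pollen index as a covariate gave 587 for LL, 254 for LL in NIL DOG6, and 1 list for LL. Without the 3 SL arrays numbered 2, LL called 856, and 47, 2 and 270 within NILs DOG1, DOG3 and DOG6. Without the 2 arrays of lowest weight, NIL DOG6 N0 number 2 and NIL DOG1 LL number 3, N0 called 703 in NIL DOG6 and LL 365 in NIL DOG1. By fry 17, 11 and 6 lists passed for 15C, N0 and LL, and with an estimated correlation 3 for N0 and 0 for LL.

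The replicate block, the array numbers as a fixed term, gave 7053, 3277 and 1827 for 15C, N0 and LL, and 7 for LL in NIL DOG3. The labels describe a randomized complete block design and do not say whether the numbers are its blocks. The numbers were not taken as a pairing, since the deviations of arrays of equal number correlated above 0.1 in 5 of 26 pairs. By mean correlation 20 of 44 arrays were most like the arrays of their own number, and neither count excludes blocks. The SL arrays numbered 2 had the highest pollen index of the SL arrays of their NIL (1.22, 1.39 and 0.92 in NILs DOG1, DOG3 and DOG6).

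Removal of 1 array at a time gave 6539 to 6859 for 15C, 2731 to 3440 for N0 and 1201 to 2023 for LL. In NIL DOG1 15C ranged from 1724 (without 20C number 2) to 2321, N0 from 398 to 628 and LL from 32 to 308. In NIL DOG3 N0 ranged from 370 to 638 and LL from 0 to 6, and in NIL DOG6 N0 from 605 to 1485 and LL from 100 to 679. NIL by condition ranged from 4 to 10 at 15C, 0 to 1 under N0 and 0 to 6 under LL. Counts moved over 1.5 times without 20C numbers 1 (506) and 2 (422) or N0 numbers 2 (398) and 3 (492) for N0 in NIL DOG1, N0 number 2 (436) or 3 (370) in NIL DOG3, and 20C number 1 (794), 2 (795) or 3 (796) or N0 number 2 (605) in NIL DOG6. For LL these were each array of NIL DOG1 (LL 80, 32 and 308, SL 61, 63 and 50 for numbers 1, 2 and 3), LL number 3 (1) and SL numbers 1 (0) and 2 (2) of NIL DOG3, and LL number 1 (100) and SL number 2 (190) of NIL DOG6. For NIL by condition at 15C these were 15C numbers 1 (7) and 2 (4) of NIL DOG1, 15C number 3 (6) and 20C numbers 1 (5) and 3 (5) of NIL DOG3, and 15C number 2 (7) and 20C numbers 1, 2 and 3 (7 each) of NIL DOG6. For NIL by condition under N0 it was N0 number 2 of NIL DOG6 (1), and under LL these were LL number 2 (2) and SL number 3 (2) of NIL DOG1, and LL numbers 1 (0) and 2 (2) and SL numbers 1 (6), 2 (0) and 3 (0) of NIL DOG6.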

Other observations

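The comparison of N0 with LL effects, and of the 2 controls with each other, was chosen after the data were seen. Genes that N0 and LL moved in opposite directions included genes of sulphur limitation and germin-like proteins. LSU1 rose by 1.73 ± 0.22 under N0 (n = 8 and 9) and fell by 1.78 under LL (SE 0.21, n = 9 and 9), and BGLU28 had 1.87 ± 0.21 and -0.76 ± 0.21. The LL call of BGLU28 was lost with the pollen index as a covariate, with which its values correlated within groups at r = 0.28. ACR6 had 1.46 ± 0.11 and -1.10 ± 0.11, AT1G30190 1.31 ± 0.13 and -1.11 ± 0.12, and AT1G72570 1.08 ± 0.13 and -1.06 ± 0.12. In the other direction GLP6 had -1.37 ± 0.25 under N0 and 1.43 ± 0.24 under LL, AT5G39110 -1.27 ± 0.34 and 1.89 ± 0.32, and the tubulin gene TUB3 -0.77 ± 0.15 and 0.80 ± 0.15. All of these changed at 15C in the direction of N0, LSU1, BGLU28, ACR6, AT1G30190 and AT1G72570 by 2.29, 2.83, 0.90, 1.42 and 1.27, and GLP6, AT5G39110 and TUB3 by -0.84, -1.21 and -1.45 (n = 9 and 9). GSTF7 and AT5G41761, also opposite under N0 and LL, were not called at 15C (-0.11 and -0.33, adjusted p = 0.837 and 0.154). Of 593 probe sets called in both, 528 (89.0%) had opposite signs, against 105 expected of independent lists. Of 824 called in both 15C and LL, 646 (78.4%) had opposite signs, against 223 expected, with a correlation over all probe sets of -0.0613 (-0.182 over those that did not follow the pollen index), against -0.236 for N0 and LL. The 15C and N0 comparisons share the 20C arrays, so this is not an independent observation.

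Seed of the 20C and SL controls differed in 7 probe sets, 3 higher and 4 lower in 20C (2299 at an unadjusted p under 0.05; n = 9 and 9). AT1G54575 differed by -1.05 ± 0.17, AT3G09440 by -0.75 ± 0.15, COR413-PM1 by -0.45 ± 0.08 and AGT3 by -0.35 ± 0.07. AT3G52740 was higher in 20C by 0.33 ± 0.06, and AT2G07752 and ATMG00800, whose values were identical, by 0.67 ± 0.12.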
